A study of Mus musculus with 2 samples.

How the data were processed

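Single-cell RNA sequencing libraries were made from the tongue epithelium of male mice aged 8 to 12 weeks, collected at 2 Zeitgeber times (ZT), ZT0 being lights on and ZT12 lights off in the usual convention. Per the labels' protocols, the minced epithelium was digested with TrypLE, a recombinant trypsin-like enzyme, and living cells were sorted by exclusion of 7-AAD before 10x Genomics 3' libraries were prepared. There was 1 library per time. The number of mice behind each library is not given in the sources used here, so no spread between animals can be stated.

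The deposited values were raw UMI counts (unique molecular identifiers, one per captured transcript) for 32285 genes, with the same gene table in both libraries. Per the submitters' processing notes, Cell Ranger 2.1.1 and the mm10 genome build were used. Per the file headers, the deposited matrices were written by Cell Ranger 4.0.0. The 2 versions differ and the discrepancy could not be settled. The annotation release behind the gene table is not given in the sources used here. Gene positions were taken by Ensembl identifier from GENCODE M21, which is on the same assembly, and 32158 of the 32285 identifiers were found there. The counts were taken as deposited, without correction for free RNA.

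The ZT0 matrix held 1726 barcodes with 49826740 UMIs and the ZT12 matrix 2819 barcodes with 67901140 UMIs. Barcodes with fewer than 500 genes or with 10% or more mitochondrial UMIs were removed, which took 129 at ZT0 and 191 at ZT12. Scrublet, run in each library through scanpy 1.11.5, called 4 and 6 doublets, or 0.25% and 0.23%. These were removed, but so low a rate means that doublets were in effect not removed. The remaining 1593 and 2622 cells were analysed.

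Counts were scaled to 10000 per cell and log transformed. The 2000 most variable genes were chosen within each library and ranked over both, leaving out clock, immediate early, heat shock, mitochondrial, ribosomal and sex-linked genes. The cells of both libraries were clustered together on 30 principal components with 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2), without integration, because library and time are the same factor. Clusters were named from marker lists fixed before the data were examined. The scoring rule, and the joining of differentiating and cornified markers into a differentiated-like class, were chosen after the clusters were seen. Clusters whose leading genes belonged to another kind stayed unnamed.

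Class shares carry exact Clopper-Pearson 95% intervals, and ratios of shares or counts carry exact conditional binomial intervals. These intervals cover counting error only. With 1 library per time no test was made and no p-value is given, and a difference between the libraries has no replicate check. For genes, UMIs were summed over cells per library, in all cells and in each class with at least 100 cells per library, and expressed as CPM, the usual scaling to the total count of the library or class. A gene met the size rule when its mean CPM was at least 50, its log2 ratio of CPM plus 1 was at least 1 in size, and the 95% interval of its ratio excluded 1. The genes named were the 10 with the largest ratio in each direction among those that met the rule, the clock genes, and up to 4 members of each gene list with the largest ratio among members of mean CPM 20 or more. In all cells, a gene was named as leading only if its ratio had the same sign in every class compared where its mean CPM was at least 5. Genes named outside this rule are marked as chosen after their values were seen. A clock gene, and the list that holds it, are not reported.

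For each of 26 gene lists fixed before the data were examined, the median log2 ratio over members of mean CPM 5 or more is given with its percentile among 10000 random lists matched on mean CPM in 20 bins, as a description of these libraries. Members are counted as higher or lower when their ratio was at least 1.5. For the share of cycling cells, each cell was thinned to 12500 UMIs, and 132 ZT0 and 261 ZT12 cells below that depth were left out. The planned measure, 2 or more UMIs over a list, was met by nearly every cell, so cells with at least 20 S list UMIs or at least 100 G2/M list UMIs were counted as well. Both of these limits were set after the data were seen.

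The size rule was tested on simulated counts for 32285 genes at the depth of all barcodes, with 200 genes changed. All 69 genes changed 2.5-fold and all 74 changed 4-fold met the rule, and none of the 57 changed 1.5-fold did. The 2-fold limit and the depth fix this outcome, so it checks the computation of the rule and covers no spread between animals or libraries. Alternatives covered the cell filter, doublets, clustering resolution, scaling (including edgeR 4.0.16 TMM), minimum CPM, pseudocount, averaging over cells, and class makeup weighted alike. For the last, each class was weighted by its share of the cells of both libraries together, with the same weights in each library.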

Results

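The series profiled single epithelial cells of the mouse tongue at ZT0 and ZT12, with the question of how cell populations vary over the day. After filtering, the ZT0 library held 1593 cells and 49254384 UMIs, with a median of 28365 UMIs and 5207 genes per cell. The ZT12 library held 2622 cells and 67122688 UMIs, with a median of 23088 UMIs and 4716 genes. There was 1 library per time, so every difference given is a difference between 2 libraries, and intervals cover counting error only.

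Most cells carry a clock in which BMAL1 and CLOCK switch on their own repressors, so activator and repressor genes peak at different times of day. The clock genes given here differed between the libraries. All 12 measured genes with an evening peak were higher at ZT12, each by at least 1.5-fold, with a median log2 ratio of 2.40, above all 10000 matched random lists. Dbp, a PAR bZip transcription factor driven directly by the clock (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203, mm10), was at 3.53 CPM at ZT0 and 194 CPM at ZT12, a ratio of 54.8 (95% interval 47.2 to 64.0). The period gene Per3 was 8.80 times higher at ZT12 (8.11 to 9.57), the Dbp relative Tef 7.87 times (7.22 to 8.59), and the repressors Nr1d2 and Nr1d1 6.91 times (6.25 to 7.66) and 5.51 times (5.03 to 6.03). Arntl, which encodes BMAL1 (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), was at 22.9 CPM at ZT0 and 1.62 CPM at ZT12, 14.1 times higher at ZT0 (11.6 to 17.4). Its partners Npas2 and Clock were 6.99 times (5.32 to 9.30) and 1.62 times (1.55 to 1.69) higher at ZT0, and the repressor Cry1 2.20 times (2.04 to 2.38).

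The clock difference was present in every keratinocyte class compared. The evening list had a median log2 ratio of 2.52 in basal-like, 2.38 in differentiated-like and 2.25 in filiform-like cells. Cry1 was 4.46 times higher at ZT0 in basal-like cells (3.63 to 5.52) and 1.84 times in differentiated-like cells (1.66 to 2.03). With 12500 UMIs per cell, Dbp was detected in 4.18% of ZT0 cells and 79.2% of ZT12 cells (8.66% and 88.2% before thinning). No class lacked Dbp at ZT12, so the background could not be read from these libraries for it.

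**Figure D1:**
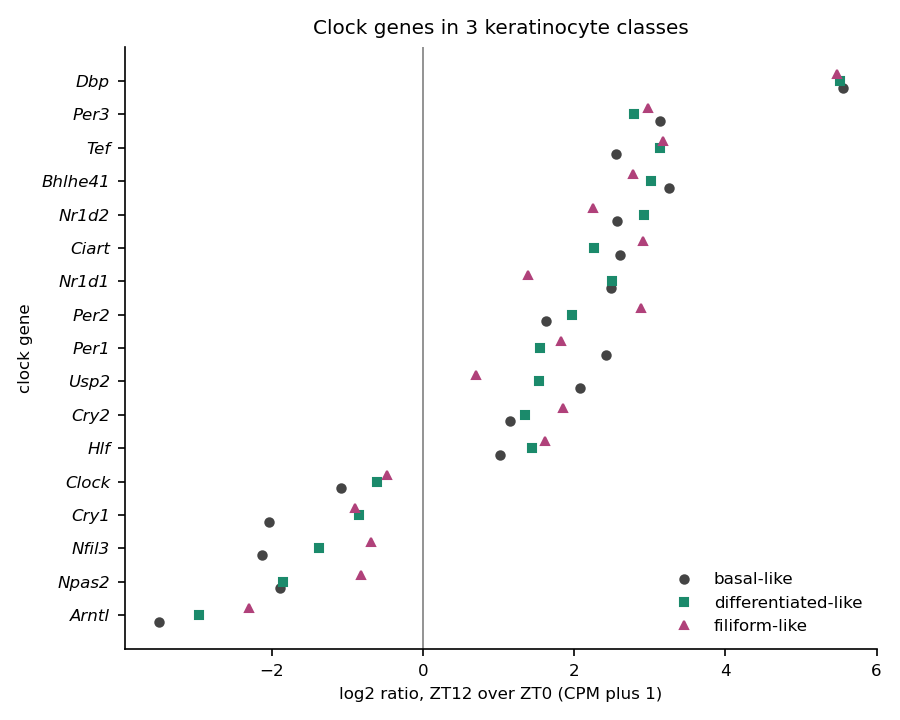
Log2 ratio (CPM plus 1, ZT12 over ZT0) of clock genes in basal-like, differentiated-like and filiform-like cells, 1 library per time and no error bars. Dbp lies above 5 in all 3 classes and Arntl lies between -3.49 and -2.29.

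The epithelium renews itself from its basal layer, whose cells divide, move up and differentiate. The cells fell into 20 clusters, most of them keratinocytes. Basal-like cells, which carry the marker Krt5 of that layer, were 29.1% of ZT0 cells (26.9 to 31.4) and 28.8% of ZT12 cells (27.1 to 30.6). Differentiated-like cells, with Krt13 and Krt4, were 38.5% (36.1 to 41.0) at ZT0 and 52.0% (50.1 to 53.9) at ZT12. The ratio was 1.35 (1.23 to 1.49). Other differentiating markers were not all highest there. Krtdap was at 1800 CPM in differentiated-like and 3039 CPM in filiform-like cells, and Sbsn at 905 and 2427 CPM, while Calml3 and Tgm3 went the other way. Of the cornified envelope markers, Lor, Crct1, Sprr3 and Cnfn were among the leading genes of cluster 4, a part of this class. Filiform-like cells, which as a class carry hair-type keratins of the filiform papillae, were 9.67% and 9.92%. Of these 154 ZT0 and 260 ZT12 cells, 41 and 54 sat in cluster 13, with a median of only 2091 UMIs. The filiform-like shares thus include shallow barcodes. The hair-type keratins were uneven in this class: Krt84 was at 11928 CPM in cluster 18, of 39 cells, against 72.6 CPM in other cells. Krt36 was at 22091 CPM in cluster 18 and 3317 CPM in the larger cluster 6. Lef1, Tchh and Padi1, of the same marker list, were lower in filiform-like than in differentiated-like cells. Krt14, another basal marker, was at 11006 CPM in basal-like and 18019 CPM in filiform-like cells, so it did not set these classes apart. Proliferating-like cells were 12.6% (10.97 to 14.28) at ZT0 and 3.70% (3.01 to 4.49) at ZT12, 3.39 times more frequent at ZT0 (2.65 to 4.37). Their log2 ratio of -1.76 kept its direction but lay between -3.61 and -2.14 under 5 alternatives of filtering and clustering. The class joined clusters that went opposite ways: cluster 8 was 11.7% of ZT0 and 1.60% of ZT12 cells, and cluster 15 was 0.879% and 2.098%. Langerhans/myeloid-like cells numbered 21 at ZT0 and 10 at ZT12, or 1.32% and 0.38%. This class also carried lymphocyte markers, with Cd3g at 320 CPM, Nkg7 at 400 CPM and Gzmb at 305 CPM, while Cd79a was at 0. Its share is therefore not that of myeloid cells alone.

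The unnamed clusters 11, 14 and 16 held 8.79% of ZT0 and 5.15% of ZT12 cells, and a rule set after the clusters were seen kept them out of the classes. Clusters mostly from 1 library made up part of the named classes. In the basal-like class cluster 9 had 215 ZT0 and 6 ZT12 cells and cluster 3 had 4 and 324. In the differentiated-like class cluster 10 had 152 and 3 and cluster 12 had 2 and 115. The basal-like share depended on how such clusters were named: with at least 1000 genes and under 5% mitochondrial UMIs the ZT12 to ZT0 ratio was 1.83 (1.58 to 2.13), and without the 5% of cells with the highest doublet scores it was 0.57 (0.50 to 0.65). The basal-like comparison is therefore not settled by these libraries. Within the differentiated-like class cluster 0 went from 7.66% (6.40 to 9.08) of ZT0 cells to 21.3% (19.7 to 22.9) of ZT12 cells, which is as large as the difference of the whole class. No marker of its class was among the leading genes of cluster 0, which included the clock outputs Usp2 and Hlf. The ratio for differentiated-like cells stayed between 1.26 and 1.37 under the alternatives, and the sort and digestion can set any of these shares.

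**Figure D2:**
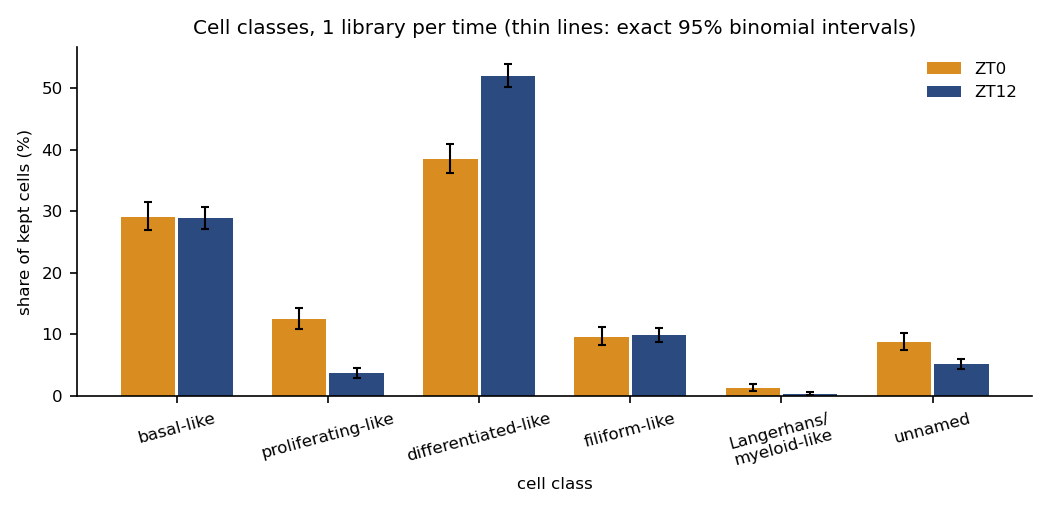
Share of kept cells (%) in each class at ZT0 (1593 cells) and ZT12 (2622 cells), with exact 95% binomial intervals. Proliferating-like cells stand at 12.6% and 3.70%, and differentiated-like cells at 38.5% and 52.0%.

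A dividing cell copies its DNA in S phase and prepares and carries out mitosis in G2/M, each with its own set of transcripts. Cells with high G2/M transcripts were more frequent at ZT0, and basal-like cells with high DNA replication transcripts were more frequent at ZT12. In cells thinned to 12500 UMIs, 172 of 1461 ZT0 cells (11.8%, 10.2 to 13.5) and 31 of 2361 ZT12 cells (1.31%, 0.89 to 1.86) had at least 100 G2/M list UMIs, a ratio of 8.97 (6.09 to 13.6). Among basal-like cells, 68 of 437 at ZT0 (15.6%, 12.3 to 19.3) and 244 of 667 at ZT12 (36.6%, 32.9 to 40.4) had at least 20 S list UMIs, 2.35 times more at ZT12 (1.79 to 3.12). The proliferating-like class held 148 of the 230 S-high cells at ZT0 and 73 of 351 at ZT12, so this ratio also depends on which cells the clustering placed in the basal-like class. The background for the S measure was 0.68% and 0.77% in differentiated-like cells. Over all cells the S-high shares were 15.7% and 14.9%, a ratio of 0.94 (0.80 to 1.12). Of the cells with high G2/M counts, 137 of 172 at ZT0 and 20 of 31 at ZT12 also passed the S limit, and cells high for the S list alone were 6.37% at ZT0 and 14.02% at ZT12. By another measure, at least 2 UMIs over the proliferation markers, 27.2% of ZT0 and 13.4% of ZT12 cells counted, 2.04 times more at ZT0 (1.75 to 2.37). In basal-like cells this measure went against the S list, at 29.98% and 21.7%, beside 5.44% and 3.60% in differentiated-like cells.

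The S limit divides a continuous range, while at ZT0 the G2/M limit lies in a sparse stretch between a larger and a smaller group of cells. At ZT0 18.7% of cells had 13.7 to 16.6 G2/M list UMIs, 0.14% had 89.3 to 107.7 and 2.81% had 228 to 275. At ZT12 these shares were 20.8%, 0.21% and 0.085%. Among basal-like cells 42 at ZT0 and 79 at ZT12 lay within 25% of the S limit, and 7 and 24 of all cells lay within 25% of the G2/M limit. At 150 G2/M UMIs the ratio was 14.5 (8.86 to 25.01) and at 50 it was 4.14 (3.15 to 5.48). For S-high basal-like cells the ratio was 1.33 (1.12 to 1.58) at 10 UMIs and 3.25 (2.04 to 5.39) at 40. The planned limit of 2 UMIs was met by 96.1% and 96.6% of cells for the S list and by 100% for the G2/M list, so it separated nothing.

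**Figure D3:**
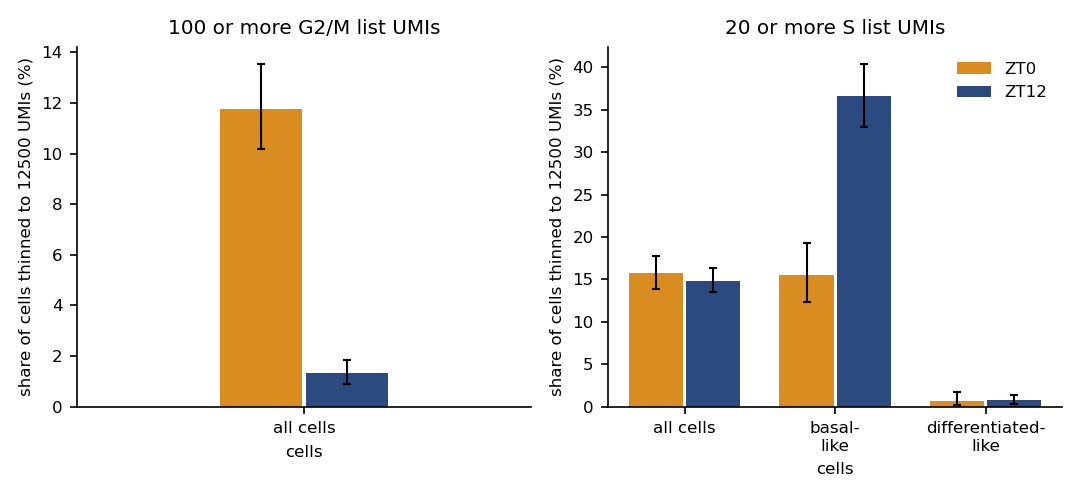
Share (%) of cells thinned to 12500 UMIs with at least 100 G2/M list UMIs in all cells (left) and at least 20 S list UMIs in 3 cell groups (right), with exact 95% binomial intervals. The G2/M shares are 11.8% at ZT0 and 1.31% at ZT12, and the basal-like S shares are 15.6% and 36.6%.

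The S and G2/M lists hold the genes whose UMIs set the S-high and G2/M-high cells above. Their medians restate that division gene by gene and are no separate support for it. In all cells 46 of 52 measured G2/M genes were lower at ZT12, with a median log2 ratio of -2.48, below all 10000 random lists. Ube2c, which drives ubiquitination by the anaphase-promoting complex (ENSMUSG00000001403, chromosome 2, 164769898 to 164778822), was 19.3 times higher at ZT0 (17.6 to 21.2), the spindle protein gene Nusap1 18.4 times (16.0 to 21.3), Cenpf 10.7 times (9.90 to 11.5) and cyclin B1 (Ccnb1) 10.9 times (9.73 to 12.3). Nusap1 was at most 1.31 CPM in the basal-like, differentiated-like and filiform-like classes. With class makeup weighted alike the G2/M median was -0.97, and in differentiated-like cells it was -0.09 over the 20 members of 5 CPM or more. The S list was at -0.17 in all cells, at 0.45 with classes weighted alike, and at 0.66 in basal-like cells, where 20 of 38 measured genes were higher at ZT12 and 1 was lower. Among these, chosen after their values were seen, the replicative helicase genes Mcm2 (15.03 to 51.4 CPM from ZT0 to ZT12), Mcm3 (21.8 to 69.7) and Mcm5 (15.7 to 43.0) were higher at ZT12.

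Interferons switch on antiviral genes and the MHC class I genes that show peptides to T cells. The interferon list and the antigen presentation list, which holds class I genes, were higher at ZT0 in each keratinocyte class compared. Antigen presentation median log2 ratios were -1.84 in basal-like, -1.59 in differentiated-like and -1.06 in filiform-like cells. In filiform-like cells 9 of 10 measured interferon and 8 of 10 measured antigen presentation genes were lower at ZT12. All 18 measured interferon genes were lower at ZT12 in all cells, with a median log2 ratio of -2.75, below all random lists. The median was -2.49 in basal-like, -3.07 in differentiated-like and -1.94 in filiform-like cells. Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680) was at 577 CPM at ZT0 and 23.7 CPM at ZT12, 24.4 times higher at ZT0 (23.2 to 25.7). The ubiquitin-like modifier Isg15 was 18.9 times higher (16.8 to 21.4) and Oasl2 21.9 times (18.4 to 26.2). Isg15 is among the leading genes of cluster 10, which came mostly from ZT0. Of the antigen presentation list 13 of 14 measured genes were lower at ZT12, with a median of -1.87. B2m, the light chain of MHC class I (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083), was at 375 and 29.1 CPM. It was 12.9 times higher at ZT0 (12.3 to 13.5), and the immunoproteasome gene Psmb8 21.1 times (17.8 to 25.2). H2-K1 was 3.91 times higher at ZT0, and its ratio of ZT12 over ZT0 had an interval of 0.24975 to 0.26144. Class I genes and Ifi27l2a have close relatives that can share reads.

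With 12500 UMIs per cell B2m was detected in 71.4% of basal-like cells at ZT0 and 23.7% at ZT12, and in 65.1% and 21.7% of differentiated-like cells. No class lacks B2m, so its background was not read. The MHC class II chaperone gene Cd74 was 4.89 times higher at ZT0 in all cells (4.65 to 5.15), beside the larger share of Langerhans/myeloid-like cells, and was at most 1.03 CPM in the 3 keratinocyte classes. Without clusters of 1 library the interferon median was -1.68. Among the genes past the size rule in all cells, Chil4, a chitinase-like lectin (ENSMUSG00000063779, chromosome 3, 106201490 to 106219507), had the largest ratio, with 16394 UMIs at ZT0 and 17 at ZT12. Cluster 10, a differentiated-like cluster with 152 ZT0 and 3 ZT12 cells, carried most of these, at 2551 CPM against 7.28 CPM in other cells. Chil4 was thus a feature of a cluster of the ZT0 library. At ZT0 at least 1 UMI was found in 16.8% of differentiated-like, 6.68% of basal-like and 15.5% of proliferating-like cells, at median depths of 38151, 22994 and 38374 UMIs. With 12500 UMIs per cell these shares were 10.5%, 4.12% and 8.06%. The 103 differentiated-like cells with a Chil4 UMI held 16149 UMIs, and the 31 basal-like cells held 39. Chil4 can share reads with its relative Chil3, which had 61 UMIs at ZT0 and 0 at ZT12.

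**Figure D4:**
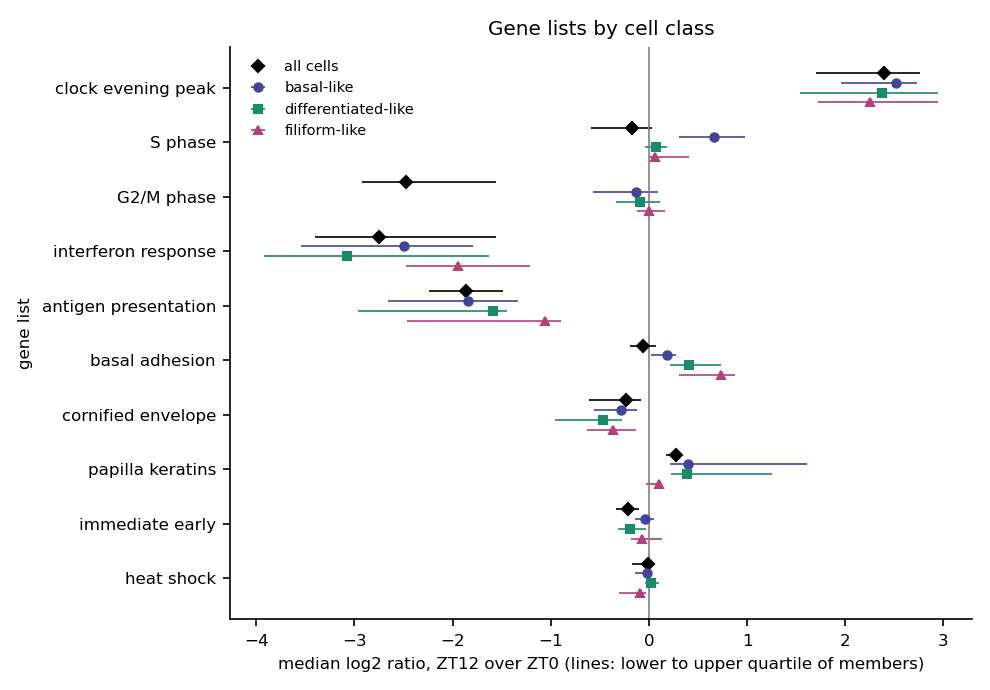
Median log2 ratio (CPM plus 1, ZT12 over ZT0) of 10 gene lists in all cells and in 3 classes, with lines from the lower to the upper quartile of members. Interferon medians lie between -3.07 and -1.94 and the S list stands at 0.66 in basal-like cells.

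In all cells 33 of 2831 genes with mean CPM of at least 50 met the size rule, 9 higher and 24 lower at ZT12. Of the 33, 29 had 1 sign in every class compared where their mean CPM was at least 5. The proliferating-like class, with 97 ZT12 cells, was not compared. Cd74 was below 5 CPM in every class compared, and Ube2c in the differentiated-like and filiform-like classes, so their signs were not checked there. For such genes the rule cannot tell a difference within classes from one of cell makeup. Besides Dbp, Per3, Tef and the clock output gene Usp2, those higher at ZT12 were glutamine synthetase (Glul, 2.57 times, 2.46 to 2.70), the cytochrome P450 gene Cyp2f2 (2.37 times, 2.31 to 2.43), the cell cycle regulator Rgcc (2.33 times, 2.22 to 2.45), cyclin D2 (Ccnd2, chromosome 6, 127125162 to 127152193, 2.24 times, 2.20 to 2.29) and the taurine transporter gene Slc6a6 (2.09 times, 2.04 to 2.15). Cyp2f2 and Usp2 are among the leading genes of cluster 0, and Glul, Ccnd2 and Dbp of cluster 3, both mostly from ZT12. Those lower at ZT12 also included the proliferation marker Mki67 (6.33 times higher at ZT0, 5.96 to 6.74), Pclaf (5.46 times, 5.14 to 5.79) and Hist1h2ap (13.6 times, 12.5 to 14.9), a histone gene with close copies. Top2a, Stmn1, Smc4 and Ptn met the rule but did not have the same sign in every class. With class makeup weighted alike 10 genes were lower, and 16 genes were shared with the 33.

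Within classes 26 genes met the rule in basal-like, 22 in differentiated-like and 13 in filiform-like cells. In basal-like cells Igfbp4 was 2.71 times higher at ZT12 (2.48 to 2.96) and Iffo2 2.42 times (2.21 to 2.65), while Ifitm3 was 3.21 times (3.09 to 3.34) and Hopx 2.59 times (2.46 to 2.72) higher at ZT0. In differentiated-like cells the hemidesmosome linker gene Dst was 2.57 times (2.46 to 2.69), Krt17 2.34 times (2.22 to 2.46) and Igfbp5 2.11 times (1.97 to 2.27) higher at ZT12. The cornified envelope gene Lor was 6.19 times higher at ZT0 there (5.65 to 6.78). Clusters 9 and 3 hold much of the basal-like class at ZT0 and ZT12, and clusters 10 and 12 part of the differentiated-like class. Cluster 0 held 122 of 614 differentiated-like cells at ZT0 and 558 of 1364 at ZT12. These values therefore also follow the states that define those clusters, and the part that does was not separated. Igfbp4 is among the leading genes of cluster 3, and Ifitm3 of cluster 9. Dst also leads cluster 3, but that cluster is basal-like and the Dst value above is from differentiated-like cells.

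Differentiation and stress lists differed by smaller amounts. The cornified envelope list, the proteins that seal the outermost cells, was at -0.23 in all cells (percentile 0.2) and had a median log2 ratio of -0.47 in differentiated-like cells, below all random lists, with 7 of 15 measured genes lower at ZT12. In all cells it was at -0.41 over members of at least 50 CPM and at -0.57 with classes weighted alike. Krtdap was 1.84 times higher at ZT0 there (1.82 to 1.86). The basal adhesion list was at 0.41 in differentiated-like and 0.74 in filiform-like cells, and papilla keratins at 0.38 and 0.10. In all cells they were at -0.06 (percentile 16.3) and 0.28 (99.98), and papilla keratins were at 0.12 with classes weighted alike. Cluster 0 made up more of the differentiated-like class at ZT12, and its part in the medians of that class was not separated. The immediate early list, a sign of dissociation stress, was at -0.21 in all cells (percentile 0.05) with 0 of 19 genes past 1.5-fold, and at -0.069 with classes weighted alike. Fos was 1.37 times higher at ZT0 (1.35 to 1.39). Heat shock genes were at -0.01 (33.1).

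The other lists had medians between -0.34 and 0.21 in all cells, given with percentiles in parentheses. Medians were -0.13 for glucocorticoid response (3.65), 0.21 for desmosome (99.9), -0.21 for Wnt response (0.46), -0.03 for Notch (41.3) and -0.34 for antimicrobial defence (0.15). The EGFR and AP-1 growth factor list was at -0.18 (1.72), and at 0.10 over members of at least 50 CPM. Medians were 0.06 for glycolysis (78.0), 0.05 for cholesterol synthesis (88.3), 0.01 for fatty acid and barrier lipid (74.7), -0.10 for NRF2 and glutathione (1.31), -0.21 for the unfolded protein response (0.06), and 0.07 for p53 targets (92.2). Oxidative phosphorylation was at -0.12 (0), mitochondrially encoded genes at -0.13 (3.31), and ribosomal protein genes at -0.03 (1.44). Median-of-ratios scaling took the ribosomal median to 0.039, a shift it gave to all genes alike, whose median went from 0.01 to 0.09. Several of these medians depended on the members and weights used. Over members of at least 50 CPM the Wnt list was at -0.0078, Notch at 0.23 and fatty acid and barrier lipid at 0.18. With classes weighted alike Wnt was at -0.028, antimicrobial defence at -0.051, cholesterol synthesis at -0.16, fatty acid and barrier lipid at -0.19, and basal adhesion at 0.24. Antimicrobial defence was at -0.74 with the stricter cell filter and at -0.85 in basal-like cells. No direction in all cells is therefore read for these lists. Single genes differed more: the glucocorticoid-induced Tsc22d3 was 1.80 times higher at ZT12 (1.71 to 1.90) and Fabp5, a fatty acid binding protein, 1.70 times (1.69 to 1.71), while the defensin gene Defb4 was 2.11 times higher at ZT0 (1.97 to 2.26).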

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

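The tests of G2/M counts at 25000 UMIs per cell and of interferon genes in clusters 2 and 7 were set before their values were seen; the remaining tests in this part were chosen only after the result was seen. Of 141 named genes, the keratin gene Krt76 alone differed by at least 1.5-fold in opposite directions between classes where its mean CPM was at least 20. Its log2 ratio (ZT12 over ZT0) was 2.88 in filiform-like cells, at 21.1 and 162 CPM, and -0.85 in differentiated-like cells, at 641 and 356 CPM. Krt76 is among the leading genes of cluster 5, at 2795 CPM against 36.7 CPM in other cells. That cluster held 108 of 614 ZT0 and 183 of 1364 ZT12 differentiated-like cells, so the value in that class also follows its makeup. The filiform-like value rests on 64 UMIs at ZT0 and 741 at ZT12, in libraries where doublets were in effect not removed. The difference between the classes was not tested.

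More cells had high G2/M counts at ZT0. At 25000 UMIs per cell with the limit doubled the ratio was 12.4 (7.29 to 22.7). Only 952 ZT0 and 1135 ZT12 cells reached that depth. Proliferating-like cells had median depths of 38374 UMIs at ZT0 and 24320 at ZT12, so a larger part of the ZT12 ones was left out. That ratio therefore cannot exclude depth. At 12500 UMIs, which kept 186 of 200 ZT0 and 95 of 97 ZT12 proliferating-like cells, the ratio was 8.97 (6.09 to 13.6). Deeper ZT0 cells do not account for the difference there. Free RNA from dividing cells reaches every cell of a library, and the median ZT0 cell held 17 G2/M list UMIs (quartiles 13 and 23) at 12500 UMIs per cell, far below the limit of 100 and close to 15 at ZT12, which argues against it. A loss of all cycling cells at ZT12 would lower the S-high share over all cells as much as the G2/M-high share, and its ratio (ZT12 over ZT0) was 0.944 (0.80 to 1.12) against 0.11 (0.074 to 0.16). A loss of mitotic cells alone was not tested. An animal or library difference, with 1 library per time, cannot be told apart from the time of day; no biological explanation was tested.

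Interferon and MHC class I genes were higher at ZT0. RNA from Langerhans or myeloid cells would bring Cd74 with B2m: the excess of B2m in differentiated-like cells predicts 5827 CPM of Cd74, and the observed excess was 0.68 CPM, or 0.012% of it. Clusters of 1 library do not account for the whole difference, since in clusters 2 and 7, which both libraries share, the interferon medians were -1.43 and -1.32. These medians are over 10 and 11 measured genes, against 18 in all cells. Without clusters of 1 library the median went from -2.75 to -1.68. The members of 5 CPM or more were chosen anew for that median, so the step does not measure the part those clusters held. An animal or library difference, an immune stimulus of the ZT0 mice included, cannot be told apart from the time of day with 1 library per time, and both may contribute.

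Differentiated-like cells made up a larger share at ZT12, with cluster 0 alone going from 7.66% to 21.3%. To set aside fewer dividing cells in the total, basal-like and differentiated-like cells were taken alone, where the ratio was 1.13 (1.03 to 1.24). This total also leaves out filiform-like, Langerhans/myeloid-like and unnamed cells. The step from 1.35 down to 1.13 is therefore not a measure of the dividing cells. The ratio of 1.13 also rests on the naming of basal-like clusters, which changed with the processing. With the stricter cell filter it turned direction, with 542 differentiated-like beside 234 basal-like cells at ZT0 and 1254 beside 733 at ZT12. This ratio therefore cannot decide whether fewer dividing cells explain all of the difference. A difference in dissociation or sorting yield, with 1 library per time, cannot be told apart from the time of day.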

How the results depend on the processing

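No paired analysis was possible because no test was made with 1 library per time. Alternatives marked as added were chosen after the data were seen. Log2 ratios are ZT12 over ZT0. The ZT12 to ZT0 ratios of the differentiated-like, filiform-like and Langerhans/myeloid-like shares stayed within their counting intervals under all 10 alternatives, but the shares did not all do so. At ZT0 filiform-like cells were 5.59% without a cell filter, and Langerhans/myeloid-like cells were 3.58% at ZT0 and 1.72% at ZT12 with genes scaled within each library, where cells led by Ltf, Wfdc18 and Krt8 joined their cluster. The log2 ratio of the proliferating-like share kept its direction, at -2.14 without a cell filter, -3.61 with the stricter one, -2.88 at resolution 0.5, -2.46 without cell cycle genes and -2.76 in thinned cells. That of the basal-like share was 0.87 with the stricter filter and -0.82 without the highest doublet scores (added). There a basal cluster of 215 and of 383 cells stayed unnamed because Il1r2, a gene of the neutrophil marker list, was among its leading genes. Cells with high G2/M counts were at -2.05 for a limit of 50 UMIs and -3.85 for 150, and S-high basal-like cells at 0.41 for 10 and 1.70 for 40 (added). The planned limit of 2 UMIs was met by nearly all cells, so its alternatives say nothing about stability.

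Genes past the size rule in all cells numbered 41 higher and 415 lower without a minimum CPM, 3 and 10 with mean CPM of at least 200, where fewer genes can pass, and 10 lower with classes weighted alike. All 18 counts within classes stayed within 1.5 times. With CPM plus 10, which shrinks low genes, medians were 1.37 for evening clock, -1.40 for G2/M, -1.23 for interferon and -1.42 for antigen presentation. With members of at least 50 CPM they were 2.96 for evening clock, -0.085 for S, -1.46 for G2/M and -1.73 for antigen presentation, and the EGFR list turned to 0.10. With classes weighted alike the S list turned to 0.45 and G2/M was -0.97, interferon -2.59 and antigen presentation -1.32. Without clusters of 1 library (added) S was -0.44, G2/M -2.72, interferon -1.68 and antigen presentation -1.75. Median-of-ratios scaling took G2/M to -2.41 and ribosomal proteins to 0.039, both by the shift it gives to all genes, whose median went from 0.01 to 0.09. G2/M was -2.54 with the stricter filter. Causes not named here were not tested. Of 153 list values 115 moved by no more than 0.5 of the width of the range of their random lists. Of the 33 genes past the size rule in all cells, 32 were shared with TMM, median-of-ratios scaling and CPM plus 10 each, and 16 with classes weighted alike. Depth limits the smallest classes: 10 Langerhans/myeloid-like cells at ZT12 support no comparison of genes.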

Other observations

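Both tests in this part were set before their values were seen, from genes picked after the main results. Wee1, a kinase that holds back entry into mitosis and is known as a clock-controlled gene, was 3.17 times higher at ZT12 in basal-like cells (2.74 to 3.67), at 22.1 and 69.9 CPM. It was at 3.74 and 12.9 CPM in differentiated-like cells. With 1 library per time an animal or library difference in Wee1 stays open.

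Ccnd2 was higher at ZT12 in basal-like cells, and the larger share of S-high cells there could have been its source. Among basal-like cells below the S limit, 369 at ZT0 and 423 at ZT12, Ccnd2 was at 661 and 1333 CPM, a ratio of 2.02 (1.93 to 2.105), so the share of S-high cells alone does not account for the difference. The cells compared sat in different clusters: cluster 3, which Ccnd2 helps to define (1844 against 320 CPM in other cells), held 324 of 756 ZT12 and 4 of 464 ZT0 basal-like cells, and the basal-like Wee1 values come from the same clusters. Ccnd1, chosen after its value was seen, was 1.75 times higher at ZT12 in the same cells (1.66 to 1.84). Within S-high basal-like cells, Mki67 was at 34.1 CPM in 68 ZT0 cells and 6.56 CPM in 244 ZT12 cells, also a comparison picked after its value was seen.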
